A study of Mus musculus with 16 samples.

How the data were processed

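RNA sequencing of mouse pancreatic tumours grown from KPC1199 cells was labelled in 16 samples. Of these, 8 were tumour tissue and 8 were cells of the line sorted from such tumours. Total RNA was extracted with TRIzol and sequenced on an Illumina platform, per the labels' protocols. The groups, taken from the sample descriptions, were tissue WT and tissue Ly6d overexpression (4 samples each) and sorted WT, sorted overexpression, sorted Ly6d-high and sorted Ly6d-low cells (2 samples each). Values were matched to the sorted groups only, so tissue overexpression against WT, and the overexpression effect in sorted cells against that in tissue, were not analysed here.

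Per the submitters' processing notes, the authors used fastp, HISAT2, featureCounts and DESeq2, without versions, and the build mm9. The gene coordinates in the deposited tables are not those of that build: of 54532 genes, 54409 were found in the GENCODE annotation of GRCm38, and 98.3% of these had the same chromosome, start and end. Coordinates are given as in the tables and named GRCm38. Whether reads were counted by strand is not given in the sources used here.

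The deposited table of sorted WT and overexpression cells holds raw counts per gene, as whole numbers. The deposited table of Ly6d-high and Ly6d-low cells holds TPM, which the authors computed over the gene length listed beside each gene, and the TPM columns have equal sums. The length column of each deposited table gives bases of the gene model and is of no other unit. Both tables list the same 54532 genes. The names of 27 genes differed between the tables, some having been turned into dates by a spreadsheet, and names were taken from the count table. Columns were assigned by name. Both WT count columns carry the library names of the sorted WT samples. The overexpression count columns carry a library name that the labels use for overexpression tumours. The labels give the sorted overexpression samples another library name, so the assignment of these columns to that group is an inference from the names and was not checked otherwise. Their names end in 1 and 2, which are used here only as names, since neither column could be matched to a single sample. A further 2 columns of per-sample counts matched no label and were not used.

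Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, libraries were scaled by TMM, and the quasi-likelihood test (glmQLFit, glmQLFTest) compared overexpression with WT. Standard errors of its log2 fold changes were taken as the fold change divided by the square root of the F statistic. TPM are not counts, so Ly6d-high and Ly6d-low cells were compared with limma 3.58.1 (limma-trend) on log2(TPM + 1), a pseudocount of 1, over genes at 1 TPM or more in at least 2 of the 4 libraries. Differences from that test are on the log2(TPM + 1) scale and understate the change of low genes. The Benjamini-Hochberg adjusted p had to lie under 0.05 in both. The design foresaw all sorted groups of a table sharing an estimate of the spread, but each table holds only the pair of groups compared. The tables differ in unit and were normalized separately, so no test was made between them. Values are given as mean ± SD over the 2 libraries of a group.

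Gene lists were fixed before the data were examined: 51 lists with 1287 entries, of which 1282 matched a gene in the tables. They cover epithelial and stem cell states, signalling outputs, metabolism, stress, and markers of other cell types that a tumour or a sort could hold. Each was tested with camera at a preset inter-gene correlation of 0.01, adjusted over all lists with at least 3 tested members, and again with the correlation estimated. The estimated setting tests each list on the few residual degrees of freedom of 2 against 2 libraries. It lost calls also where the estimate lay under 0.01. A call lost under it therefore does not by itself show that correlation between genes made the call. Members past the threshold were counted over all genes tested and adjusted over the list alone. The genes named in the text follow a rule fixed at the same time. Per comparison it takes Ly6d, and the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 1 CPM or TPM and groups that did not overlap, leaving out predicted genes, pseudogenes and genes without a name. It also takes up to 4 members with the lowest p from each list that passed camera or had at least 3 members past the threshold. Genes outside this rule are marked as chosen after their values were seen.

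Library totals were 18108850 and 15449241 counts for WT and 18290325 and 18001470 counts for overexpression. TPM multiplied by gene length came in whole multiples of a single step per library, so reads were recovered: 100% of the 85643 values above 0 were whole within 0.1 reads, the largest deviation being 0.00015 reads. The recovered totals were 20509539 and 18362419 reads for Ly6d-high and 15063975 and 19322028 for Ly6d-low cells. These reads served to give depth, read-based ratios and alternative tests, not the main test. Where both libraries of a group were at 0, a fold was computed against 3 counts over the group and is a lower bound. Such floors, and intervals of read ratios, at a confidence level of 0.95, cover counting error only. The interval of the correlation across acinar genes comes from resampling genes. No replicate pair agreed within sampling noise: over genes with at least 20 reads in a pair, the mean chi-square per gene was 26.9 for WT, 8.66 for overexpression, 24.1 for Ly6d-high and 3.46 for Ly6d-low. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

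Each test was tested on simulated data with 200 changed genes drawn from the real means and library sizes. For overexpression against WT, with 15611 genes tested, 44.8% of genes changed 1.5-fold, 59.7% of those changed 2-fold and 81.8% of those changed 4-fold were recovered, with 7 false calls among 131. For Ly6d-high against Ly6d-low, with 14578 genes tested, the shares were 0%, 22.4% and 66.7%, with 6 false calls among 65. The simulated changes went up and down in equal numbers, whereas 88.1% of the main calls for Ly6d-high were higher. These shares therefore need not hold in the data. Alternatives set at the same time as the gene lists were RLE size factors, DESeq2 1.42.0, no filter on low counts or TPM, a pseudocount of 0.1, TMM factors on TPM, a replicate block, an estimated correlation for gene lists, a mean of at least 10 CPM and TPM for the correlation of effects, and leaving out each library in turn. Fits of only the groups compared were the same as the main ones. Tests on recovered reads, and counts without marker genes of other cell types and antigen receptor segments, were added after seeing the data.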

Results

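KPC1199 is a mouse pancreatic cancer line. The cells were implanted into the pancreas, and RNA was sequenced from tumour cells sorted afterwards. Transcriptomes were compared between WT cells and cells overexpressing Ly6d, which encodes a cell surface protein of the Ly6 family, to ask how Ly6d affects the start and growth of pancreatic cancer. A further comparison set cells sorted for high Ly6d against cells sorted for low Ly6d. Each of these 4 groups had 2 libraries. The overexpression count columns were assigned to their group from a library name that the labels use for overexpression tumours. Totals ran from 15449241 to 18290325 counts in the WT and overexpression libraries and from 15063975 to 20509539 recovered reads in the Ly6d-high and Ly6d-low libraries.

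Ly6d itself (ENSMUSG00000034634, GRCm38 chromosome 15, 74762056 to 74763620, a protein-coding gene) differed in the direction of the group names in both comparisons. The overexpression columns were assigned from a library name, and the Ly6d-high and Ly6d-low cells were sorted on Ly6d, so their difference was set by the sort. Ly6d was at 1163 ± 137 CPM in WT and 3401 ± 31.0 CPM in overexpression cells (SD, n = 2 each), a log2 fold change of 1.53 ± 0.08 (SE; edgeR quasi-likelihood adjusted p = 1.66e-07). In sorted Ly6d-low cells it was at 0.954 ± 0.852 TPM, from 7 and 2 recovered reads, and in Ly6d-high cells at 600.3 ± 137 TPM (SD, n = 2 each). The difference was 8.32 ± 0.31 on the log2(TPM + 1) scale (SE; limma adjusted p = 2.46e-05). WT cells thus carried Ly6d mRNA at a level well above 0, and overexpression raised it 2.92-fold in mean CPM. CPM and TPM come from separately normalized tables and were not tested against each other.

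**Figure D1:**
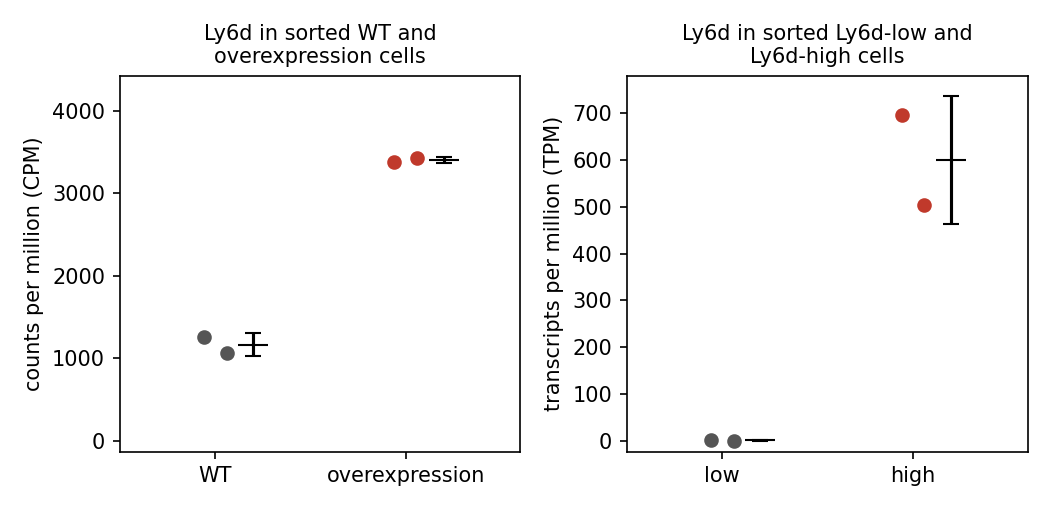
Ly6d level in each library (points) with the group mean ± SD (bar with caps), in CPM for sorted WT and overexpression cells and in TPM for sorted Ly6d-low and Ly6d-high cells, n = 2 per group. The overexpression libraries lie at 3380 and 3423 CPM against 1260 and 1066 CPM in WT, and the Ly6d-high libraries at 697 and 504 TPM against 1.56 and 0.352 TPM in Ly6d-low.

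The first comparison asked what overexpression of Ly6d changed in sorted tumour cells. Overexpression libraries held far less mRNA of digestive enzyme genes, and less of islet and endothelial genes, than WT libraries. They held more mRNA of neutrophil, macrophage and plasma cell genes. Of the lists camera called, only the acinar one kept its call with an estimated correlation. The macrophage and neutrophil lists lost theirs at estimates of -0.011 and -0.024, under the preset 0.01. Correlation between genes does not account for those losses. Of 15771 genes tested, 366 were higher and 290 lower at an adjusted p under 0.05 (edgeR quasi-likelihood test, 2 against 2 libraries).

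The acinar list, which holds the enzymes and regulators of the exocrine pancreas, fell as a whole. All 29 tested members were lower, also when adjusted over the list alone, with a median log2 fold change of -3.79. One of them, Prss1, named after its values were seen, had no reads in overexpression, and the median was -3.72 with that gene at its bound. The camera call held with an estimated correlation (adjusted p = 0.0326). Pancreatic lipase Pnlip (chromosome 19) went from 1913 ± 144 CPM in WT to 82.8 ± 0.621 CPM (log2 fold change -4.55 ± 0.09, adjusted p = 5.25e-11). The elastase Cela2a (chromosome 4) went from 2332 ± 104 to 145 ± 7.87 CPM, the chymotrypsin-like protease Ctrl (chromosome 8) from 642 ± 2.12 to 35.02 ± 0.970 CPM, and the ribonuclease Rnase1 (chromosome 14) from 569 ± 21.8 to 46.0 ± 0.612 CPM. Acinar genes took 2.82% and 2.87% of all counts in the WT libraries and 0.222% and 0.242% in the overexpression libraries. The 8 largest falls were, in order, Dusp26, Aqp12, Aass, the amylases Amy2a1 and Amy2a5, the phospholipase Pla2g1b, Pnlip and the trypsinogen gene Prss3, with log2 fold changes from -5.21 to -4.45. The amylase and trypsinogen genes have near-identical copies, so reads could be split among them. Aass rested on 30 and 35 counts in WT and lost its call without WT replicate 1 (adjusted p = 0.140) or WT replicate 2 (adjusted p = 0.344).

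Islet and endothelial genes also fell. In the endocrine list, 13 of 22 tested members were lower and none higher (median log2 fold change -0.98), and 15 were lower and 1 higher when adjusted over the list alone. Its camera call was lost with an estimated correlation (adjusted p = 0.295). Glucagon (Gcg) went from 368 ± 40.0 to 134 ± 9.56 CPM, somatostatin (Sst) from 77.3 ± 5.83 to 29.7 ± 1.42 CPM, and insulin (Ins1) from 194 ± 4.01 to 110.1 ± 6.66 CPM. In the endothelial list, 9 of 22 were lower (median -0.80), 15 lower and 1 higher when adjusted over the list alone, and the call was lost with an estimated correlation (adjusted p = 0.255). Kdr, a receptor for vascular endothelial growth factor, went from 45.6 ± 1.82 to 18.8 ± 2.08 CPM and Plvap from 104.8 ± 5.43 to 55.3 ± 1.29 CPM.

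Genes of the neutrophil, macrophage and plasma cell lists rose. In the neutrophil list, 13 of 20 tested members were higher and 1, Lcn2, named after its values were seen, was lower (median log2 fold change 3.09), with 16 higher and 1 lower when adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.138). The granule protein gene Ngp went from 0.0876 ± 0.0323 to 35.3 ± 0.732 CPM and S100a9 from 0.710 ± 0.0890 to 36.3 ± 3.49 CPM. In the macrophage list, 10 of 24 were higher (median 1.56), 18 higher and 1 lower when adjusted over the list alone, with an adjusted p = 0.142 under an estimated correlation. The lysozyme gene Lyz2 went from 21.6 ± 2.38 to 97.8 ± 4.30 CPM and complement C1qa from 4.90 ± 0.297 to 22.2 ± 0.249 CPM. In the B and plasma cell list, 4 of 8 were higher (median 3.19), 6 when adjusted over the list alone, with an adjusted p = 0.295 under an estimated correlation. Jchain, which joins secreted antibody units, went from 5.89 ± 0.646 to 74.3 ± 2.75 CPM. Camera did not call the T cell list (adjusted p = 0.0625), the cytotoxic and natural killer list (adjusted p = 0.464) or the dendritic cell list (adjusted p = 0.443). Among these lists, 1 gene, of the dendritic cell list, passed the threshold. Of the 7 T cell members tested, 6 had a log2 fold change above 0 (median 1.38), and 3 were higher when adjusted over the list alone. The 8 largest rises of all were immunoglobulin variable segments with no reads in WT: Ighv1-82, Igkv19-93, Igkv10-96, Igkv3-12, Igkv4-59, Igkv14-111, Igkv4-91 and Igkv6-13. Against a floor of 3 counts over the WT group, Ighv1-82 was at least 89.4-fold higher and Igkv6-13 at least 42.5-fold higher. Such segments resemble each other, so reads could be split among them. Immunoglobulin segments made up 78 of the 366 higher genes. The pan-leukocyte gene Ptprc, chosen after its values were seen, was at 1.82 and 1.55 CPM in the WT libraries and at 10.7 and 10.3 CPM in the overexpression libraries.

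Smaller counts of genes passed the threshold in other lists. In the fibroblast list, 3 of 25 were higher, 7 when adjusted over the list alone, and camera did not call it (adjusted p = 0.0507). In the hypoxia list, 4 of 27 were higher (median log2 fold change 0.16), 10 when adjusted over the list alone, and the call was lost with an estimated correlation (adjusted p = 0.601). Ero1l, an oxidase of the endoplasmic reticulum, went from 152 ± 3.58 to 235 ± 1.53 CPM, Ndrg1 from 346 ± 2.69 to 475 ± 13.2 CPM, and the mitophagy receptor gene Bnip3 from 37.3 ± 1.34 to 56.7 ± 2.13 CPM. In the list of Myc targets and ribosome biogenesis, 5 of 35 were lower (median -0.22), 14 lower and 1 higher when adjusted over the list alone, with an adjusted p = 0.601 under an estimated correlation. The nucleolar gene Nop56 went from 151 ± 10.2 to 114 ± 4.44 CPM and the polyamine enzyme gene Odc1 from 206 ± 12.7 to 164 ± 2.51 CPM, a call lost without WT replicate 1 (adjusted p = 0.0627). Camera also called the MHC class I list lower, with 2 of 16 members past the threshold (H2-Q6 and Psmb10), the cell cycle list lower, with 1 of 40 (the replication helicase gene Mcm3), and the erythroid list higher, with 1 of 6 (the globin gene Hbb-bs). Adjusted over the list alone, these counts were 3 lower, 8 lower and 1 higher, and 3 higher. With an estimated correlation their adjusted p were 0.613, 0.484 and 0.484. Psmb10 lost its call without WT replicate 1 (adjusted p = 0.204), and Mcm3 without WT replicate 1 (adjusted p = 0.102), WT replicate 2 (adjusted p = 0.128) or overexpression replicate 1 (adjusted p = 0.0651) and with DESeq2 (adjusted p = 0.0527). The cell cycle call was lost without overexpression replicate 1 (adjusted p = 0.0511).

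Epithelial and stem cell genes moved in both directions. In the stem and progenitor list, 5 of 27 members were higher and none lower, 7 higher and 2 lower when adjusted over the list alone, and camera did not call the list (adjusted p = 0.275). The chemokine receptor gene Cxcr4, which leukocytes also express, went from 1.83 ± 0.163 to 10.1 ± 1.28 CPM. Lgr4, a receptor for R-spondins, went from 73.9 ± 0.278 to 96.1 ± 0.555 CPM and the transcription factor gene Klf5 from 121 ± 11.2 to 158 ± 8.55 CPM. Lgr4 lost its call without WT replicate 1 (adjusted p = 0.150) or WT replicate 2 (adjusted p = 0.0883), and Klf5 without WT replicate 2 (adjusted p = 0.148). In the classical pancreatic tumour list, 3 of 27 were higher and 2 lower, 8 higher and 4 lower when adjusted over the list alone. The gel-forming mucin Muc5ac went from 48.5 ± 3.58 to 138 ± 13.6 CPM, and the trefoil factor Tff2 from 84.1 ± 5.36 to 18.3 ± 1.002 CPM. In the interferon list, 5 of 41 were higher and 6 lower, 7 and 8 when adjusted over the list alone: Ifit3 went from 48.4 ± 1.43 to 78.7 ± 2.76 CPM, and the chemokine Cxcl9 from 153 ± 8.10 to 107 ± 3.74 CPM.

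The count of calls without marker genes of other cell types and antigen receptor segments, an alternative chosen after seeing the data, was 253 higher and 236 lower. Leaving out overexpression replicate 1 gave 1584 calls and leaving out overexpression replicate 2 gave 1062, against 656 with all libraries, and no call changed its direction in either.

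The second comparison asked what set Ly6d-high apart from Ly6d-low tumour cells. Ly6d-high libraries held more Lcn2, Wfdc2, Mmp7, Rab25 and Cldn4 mRNA, and more mRNA of MHC class II, immunoglobulin, macrophage and acinar genes. Mitochondrially encoded transcripts were lower. Of the 16 lists called by camera, 0 were called with an estimated correlation. The MHC class II list lost its call at an estimate of -0.098, under the preset 0.01. The macrophage and neutrophil lists were likewise under it, at -0.069 and -0.053. For these lists, correlation between genes does not account for the loss. Other called lists had estimates far above the preset: 0.97 for ribosomal proteins, 0.55 for extracellular matrix and 0.50 for glycolysis. Hypoxia was at 0.39, oxidative phosphorylation at 0.34 and the cell cycle at 0.25. For such lists, correlation between genes may account for the call. Of 14625 genes tested, 1264 were higher and 171 lower (limma-trend on log2(TPM + 1), 2 against 2 libraries). The median difference over all genes was 0.25, so part of this asymmetry is shared by most genes. With TMM factors on TPM the median was 0.01 and 712 genes were higher and 249 lower. With edgeR on recovered reads, an alternative chosen after seeing the data, 15275 genes were tested and 1224 were higher and 591 lower. List medians of the main test are therefore given also relative to all genes.

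Among the genes that rose, Lcn2, an iron-scavenging lipocalin of epithelia and neutrophils, went from 69.2 ± 5.55 TPM in Ly6d-low to 1518 ± 126 TPM in Ly6d-high cells (log2 difference 4.44 ± 0.12 SE, adjusted p = 6.68e-06). The matrix protease Mmp7 (chromosome 9) went from 52.4 ± 5.66 to 1046 ± 139 TPM (4.29 ± 0.14, adjusted p = 1.34e-05), Wfdc2 (chromosome 2) from 3.09 ± 0.964 to 129 ± 9.76 TPM (5.01 ± 0.20, adjusted p = 2.54e-05) and complement C3 from 21.1 ± 0.894 to 243 ± 25.6 TPM. In the list of ion channels and mucosal secretion, 6 of 18 were higher and 1 lower, 8 and 1 when adjusted over the list alone, and camera did not call it (adjusted p = 0.0511). In the pan-epithelial list, 10 of 30 were higher and 5 lower, 17 and 6 when adjusted over the list alone, and camera did not call it (adjusted p = 0.115). Rab25, a small GTPase of epithelial recycling, went from 4.28 ± 0.591 to 45.1 ± 0.501 TPM, the tight junction gene Cldn4 from 13.3 ± 0.379 to 87.9 ± 9.48 TPM, and Cldn3 from 563 ± 49.9 to 1334 ± 153 TPM. The 5 lower members, chosen after their values were seen, were the keratins Krt7, Krt8, Krt18, Krt19 and Krt20: Krt19 went from 14070 ± 102 to 8936 ± 344 TPM. With TMM factors on TPM, 9 members of this list were higher and 2 lower. On recovered reads, 12 were higher and 6 lower with edgeR, and 10 higher and 6 lower with DESeq2.

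Genes of basal and classical states were split. In the basal and squamous list, 5 of 21 were higher and 2 lower, 6 and 4 when adjusted over the list alone, and camera did not call it (adjusted p = 0.168). The keratin Krt17 went from 2.03 ± 0.00166 to 41.9 ± 1.305 TPM. In the classical pancreatic tumour list, 5 of 26 were higher and 5 lower, 7 and 8 when adjusted over the list alone. The trefoil factor Tff2 went from 35.5 ± 5.29 to 130 ± 21.9 TPM, while the galectin Lgals4 went from 2083 ± 43.1 to 1019 ± 41.6 TPM and the gastric gene Gkn2 from 123 ± 2.46 to 54.3 ± 2.87 TPM. Camera called the classical list lower, although its median was 0.02 (-0.23 relative to all genes), and the call was lost with an estimated correlation (adjusted p = 0.545), without Ly6d-low replicate 1 (adjusted p = 0.188) or without Ly6d-low replicate 2 (adjusted p = 0.262). The medians of both lists turned negative with TMM factors, at -0.19 for the basal list, with 2 members higher and 5 lower, and -0.21 for the classical list, with 4 higher and 7 lower. In the Ly6 family list, which includes Ly6d, 5 of 17 were higher, 7 when adjusted over the list alone, and camera did not call it (adjusted p = 0.589). With TMM factors 3 were higher, and with edgeR on recovered reads 3 were higher and 1 lower. Ly6g6e went from 0.168 ± 0.0535 to 4.88 ± 1.55 TPM.

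**Figure D2:**
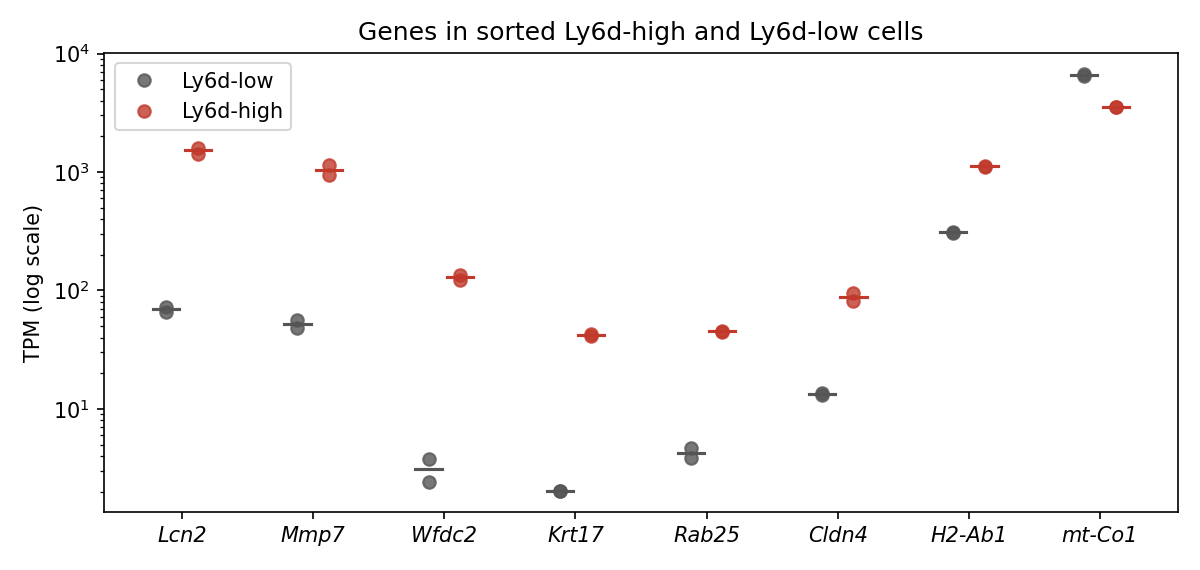
TPM of 8 genes in the sorted Ly6d-low (grey) and Ly6d-high (red) libraries, on a log scale, with each library as a point and the group mean as a line, n = 2 per group. Lcn2, Mmp7, Wfdc2, Krt17, Rab25, Cldn4 and H2-Ab1 are higher in both Ly6d-high libraries, and mt-Co1 is lower in both (3552 against 6600 TPM in the means).

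Genes of MHC class II presentation rose, and lists of inflammatory signalling were mixed. In the MHC class II list, 8 of 10 members were higher, 9 when adjusted over the list alone, with a median of 1.17 (0.92 relative to all genes), and the camera call was lost with an estimated correlation (adjusted p = 0.438). H2-Ab1 went from 309 ± 2.23 to 1116 ± 19.6 TPM (1.85 ± 0.10 SE, adjusted p = 7.51e-05) and the invariant chain gene Cd74 from 1738 ± 58.5 to 4540 ± 320.0 TPM. Macrophage and plasma cell genes were higher in the same libraries, and whether the class II transcripts came from tumour cells was not tested. With overexpression, 1 of 9 tested class II members was higher and 0 lower (median log2 fold change -0.20). Adjusted over the list alone, 1 was higher and 3 were lower. The MHC class I list had 3 of 16 higher, 6 higher and 2 lower when adjusted over the list alone, led by H2-Q6 and H2-Q7, a pair similar enough that reads could be split between them. Its median of 0.25 (0.00 relative to all genes) turned to -0.03 with TMM factors. In the list of NF-kB targets, 6 of 21 were higher, 10 when adjusted over the list alone (adjusted p = 0.855 with an estimated correlation), and its call was lost without Ly6d-low replicate 1 (adjusted p = 0.0720) or Ly6d-low replicate 2 (adjusted p = 0.148). The adhesion molecule Icam1 went from 19.5 ± 0.405 to 74.95 ± 16.8 TPM and Vcam1 from 36.0 ± 0.197 to 81.3 ± 10.5 TPM. The interferon list had 6 of 41 higher, 21 when adjusted over the list alone (adjusted p = 0.874 with an estimated correlation), and 2 higher with TMM factors. Its call was lost without Ly6d-low replicate 1 (adjusted p = 0.282) or Ly6d-low replicate 2 (adjusted p = 0.442). In the list of inflammatory cytokines and chemokines, 8 of 31 were higher and 2 lower, 12 and 2 when adjusted over the list alone, and camera did not call it (adjusted p = 0.607). With TMM factors, 1 of its members was higher and 2 were lower. Among the lists camera did not call, 7 of 24 YAP and TEAD targets were higher, 14 higher and 2 lower when adjusted over the list alone, among them Amotl2, which went from 5.83 ± 0.159 to 14.2 ± 1.57 TPM. Of 17 Wnt targets, 4 were higher, also when adjusted over the list alone, among them Tnfrsf19, which went from 1.33 ± 0.0453 to 10.9 ± 1.72 TPM.

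Transcripts of other cell types stood beside these changes. In the fibroblast list, 4 of 24 were higher, 6 when adjusted over the list alone. The myofibroblast and mural list had 3 of 13 higher, 4 when adjusted over the list alone. Camera called neither (adjusted p = 0.0621 and 0.235). In the acinar list, 22 of 29 were higher and none lower, 23 higher when adjusted over the list alone, with a median of 1.05 (0.80 relative to all genes) and an adjusted p = 0.438 under an estimated correlation. The chymotrypsinogen gene Ctrb1 went from 1073 ± 17.6 to 4140 ± 452 TPM and carboxypeptidase Cpa1 from 252 ± 1.63 to 761 ± 83.7 TPM. With TMM factors, 12 acinar genes were higher. In the endocrine list, 4 of 15 were lower and 2 higher, 5 and 3 when adjusted over the list alone: Gcg went from 437 ± 22.5 to 218 ± 0.446 TPM, and transthyretin (Ttr) from 7.89 ± 1.13 to 77.4 ± 11.6 TPM (list adjusted p = 0.659 with an estimated correlation, and 0.0860 without Ly6d-low replicate 1). In the macrophage list, 9 of 15 were higher, 13 when adjusted over the list alone (median 1.03, 0.79 relative to all genes, adjusted p = 0.438 with an estimated correlation). Lyz2 went from 10.9 ± 1.25 to 87.8 ± 4.16 TPM and Apoe from 52.5 ± 0.693 to 230 ± 10.3 TPM. The neutrophil list had 4 of 7 higher, 6 when adjusted over the list alone (adjusted p = 0.438 with an estimated correlation), namely Lcn2, Acod1, Ltf and Ly6g, of which epithelial cells also express Lcn2 and Ltf. Ly6g lost its call without Ly6d-low replicate 1 (adjusted p = 0.485) or Ly6d-low replicate 2 (adjusted p = 0.364), with TMM factors (adjusted p = 0.104), with no filter on low TPM (adjusted p = 0.112) and on recovered reads with edgeR (adjusted p = 0.240) and DESeq2 (adjusted p = 0.674). In the B and plasma cell list, 5 of 7 were higher, also when adjusted over the list alone (adjusted p = 0.659 with an estimated correlation). Camera did not call the cytotoxic and natural killer list (median -0.05, -0.30 relative to all genes, adjusted p = 0.163) or the dendritic cell list (1 of 5 higher, adjusted p = 0.727), and the T cell list had only 2 tested members, of which 1 was higher. Together with Ly6d, the 8 largest rises were the immunoglobulin genes Igkc, Ighg2c, Igha, Iglc1, Iglv1 and Ighg2b and the chitinase-like gene Chil4. Igkc went from 1.39 ± 0.230 to 1654 ± 148 TPM. Ighg2c, Iglc1, Ighg2b and Chil4 had no reads in Ly6d-low cells and were at least 1575-fold, 232-fold, 749-fold and 668-fold higher against 3 counts over that group. Immunoglobulin segments made up 84 of the 1264 higher genes, and 1125 genes were higher and 164 lower without marker genes of other cell types and antigen receptor segments.

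Mitochondrially encoded transcripts were lower, and the count of metabolic genes past the threshold depended on the scaling. Of 13 mitochondrially encoded genes, 8 were lower, 12 when adjusted over the list alone, with a median of -0.89 (-1.14 relative to all genes, adjusted p = 0.438 with an estimated correlation). The oxidase subunit mt-Co1 went from 6600 ± 187 to 3552 ± 24.8 TPM (-0.89 ± 0.07 SE, adjusted p = 0.000511) and mt-Cytb from 7423 ± 398 to 4184 ± 239 TPM. Mitochondrial genes took 1.01% and 0.874% of the reads in Ly6d-high and 1.67% and 1.67% in Ly6d-low libraries. The 8 largest falls were 4 mitochondrial transfer RNA genes (mt-Ts2, mt-Tl2, mt-Th and mt-Tg), mt-Atp6, mt-Co3, Snord7 and Mir29a. The transfer RNA genes, Snord7 and Mir29a are short and rested on at most 17 reads in any library. Snord7 lost its call without Ly6d-high replicate 2 (adjusted p = 0.0529) and with TMM factors (adjusted p = 0.0744), and mt-Atp6 with TMM factors (adjusted p = 0.0627). With DESeq2 on recovered reads, mt-Tl2, mt-Th and mt-Tg lost their calls (adjusted p = 0.165, 0.176 and 0.451), and mt-Ts2, Snord7 and Mir29a were given no adjusted p. Camera called the ribosomal protein list lower (3 of 47 past the threshold, 0 when adjusted over the list alone, median -0.34, or -0.59 relative to all genes) and likewise oxidative phosphorylation (1 of 50 lower and 2 higher, 0 when adjusted over the list alone, median -0.16, or -0.40 relative to all genes), with an adjusted p = 0.855 for both under an estimated correlation. With TMM factors the medians of these lists were -0.61 and -0.43, without a member past the threshold, while on recovered reads 5 ribosomal protein and 4 oxidative phosphorylation genes were lower with edgeR, and 18 and 8 with DESeq2. The oxidative phosphorylation call was lost without Ly6d-high replicate 2 (adjusted p = 0.233). Camera also called glycolysis, the cell cycle and hypoxia lower, with medians of 0.01, 0.05 and 0.02 (-0.23, -0.20 and -0.23 relative to all genes) that turned negative with TMM factors. With an estimated correlation their adjusted p were all 0.874. Without Ly6d-high replicate 1 these calls were lost (adjusted p = 0.0641, 0.523 and 0.266), as they were without Ly6d-low replicate 2 (adjusted p = 0.0578, 0.148 and 0.174). Without Ly6d-low replicate 1 the cell cycle (adjusted p = 0.0658) and hypoxia (adjusted p = 0.127) calls were lost. The lactate dehydrogenase gene Ldha went from 3822 ± 11.4 to 2577 ± 18.2 TPM, one of 2 lower members of the 21 in the glycolysis list, with 6 lower and 1 higher when adjusted over the list alone and a mean change of -0.04. Ldha lost its call without Ly6d-low replicate 1 (adjusted p = 0.0798) or Ly6d-low replicate 2 (adjusted p = 0.0697). Of the 40 cell cycle genes none passed the threshold, and of the 27 hypoxia genes only Car9 did, which was higher and lost its call without Ly6d-low replicate 1 (adjusted p = 0.309) or Ly6d-low replicate 2 (adjusted p = 0.173). With TMM factors, 5 hypoxia and 4 glycolysis genes were lower, and with edgeR on recovered reads 6 hypoxia, 9 glycolysis and 3 cell cycle genes were lower. DESeq2 on recovered reads gave 6, 9 and 3 as well. Car9 also lost its call with TMM factors (adjusted p = 0.0635) and DESeq2 on recovered reads (adjusted p = 0.0702). The extracellular matrix list was called higher with 2 of 34 members past the threshold, Col6a3 and Thbs1, and 0 when adjusted over the list alone (adjusted p = 0.874 with an estimated correlation). Both lost their call with TMM factors, Col6a3 at an adjusted p = 0.0743 and Thbs1 at 0.0915. Without Ly6d-low replicate 1 these were 0.228 and 0.488, and without Ly6d-low replicate 2 they were 0.125 and 0.257. Thbs1 also lost its call with a pseudocount of 0.1 (adjusted p = 0.0578) and on recovered reads with edgeR (adjusted p = 0.0531) and DESeq2 (adjusted p = 0.109). With no filter on low TPM, mt-Co1, mt-Cytb, mt-Atp6, mt-Th, mt-Tg, Snord7, Ldha, Car9, Col6a3 and Thbs1 lost their calls, at adjusted p from 0.0550 to 0.139. The list call itself was lost without Ly6d-low replicate 1 (adjusted p = 0.501) or Ly6d-low replicate 2 (adjusted p = 0.298).

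Leaving out Ly6d-high replicate 1 gave 6710 calls and leaving out Ly6d-low replicate 1 gave 931, against 1435 with all libraries, and no call changed its direction in either.

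**Figure D3:**
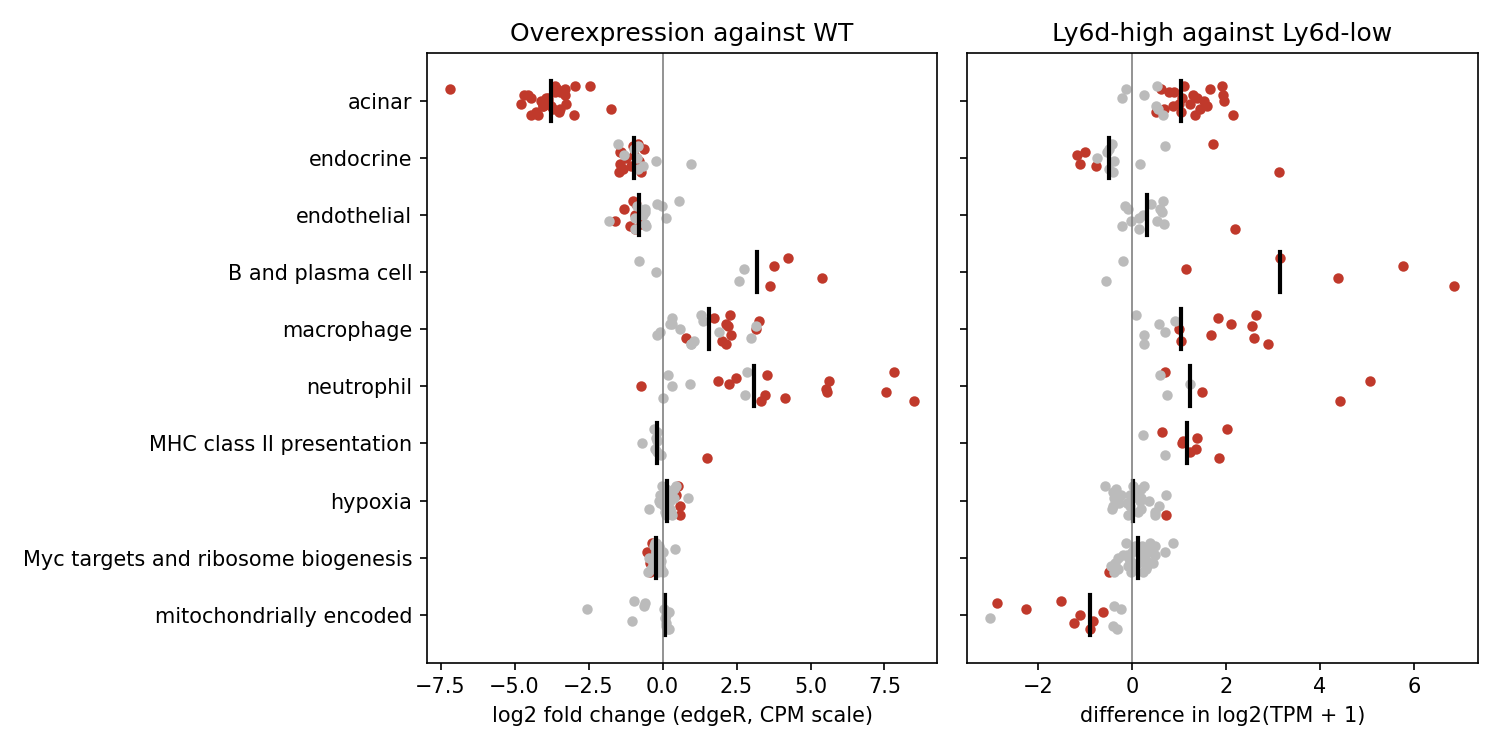
Log2 change of each tested member (points) of 10 gene lists, for overexpression against WT (left, edgeR) and Ly6d-high against Ly6d-low (right, log2(TPM + 1)). Red points have an adjusted p under 0.05, grey points do not, and black lines are list medians. Acinar genes have a median of -3.79 on the left and 1.05 on the right, and the leftmost acinar point has no reads in overexpression. Macrophage genes have medians of 1.56 and 1.03.

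A last comparison asked whether cells sorted for high Ly6d differed from Ly6d-low cells in the genes that overexpression changed. The comparisons share no library. Genes higher in Ly6d-high cells were found more often than independent lists would give, both among genes that rose and among genes that fell with overexpression. Of 13241 genes tested in both, 80 were higher in both, against 21.7 for independent lists, and 54 of the 80 were marker genes of other cell types or antigen receptor segments. A further 128 were lower with overexpression and higher in Ly6d-high cells, against 20.7 for independent lists. Of the 128, 25 were such genes. Both counts take only members of the fixed lists and antigen receptor segments. The 80 include Ly6d itself, which each comparison raised. Outside those lists, they also include the pan-leukocyte genes Laptm5, Tyrobp, Itgb2, Rac2 and Cd48, named after their values were seen. The rest of the 80 and of the 128 are therefore not shown to be genes of the tumour cells. The expected numbers take genes as independent, which genes that move together are not, and no test was made. The 128 include Cldn4 (log2 fold change -0.81 with overexpression, difference 2.63 in Ly6d-high cells), Tff2 (-2.22 and 1.84) and H2-Q6 (-0.61 and 2.74). Only 4 genes were lower in both, against 2.75 for independent lists, and 4 were higher with overexpression and lower in Ly6d-high cells, against 2.88. Across genes, which are not independent replicates, the log2 changes had a Pearson r of 0.063 and a Spearman rho of -0.059. Pearson r turned to -0.192 without marker genes of other cell types and antigen receptor segments, to -0.00715 over the 6631 genes with a mean of at least 10 CPM and TPM, to -0.0877 without Ly6d-high replicate 1 and to -0.131 without Ly6d-high replicate 2.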

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

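The tests on recovered reads and the counts without marker genes of other cell types were chosen after seeing the data. Ly6d kept its direction and its call under all alternatives run, with log2 changes from 1.42 to 1.64 for overexpression and from 7.86 to 9.42 for Ly6d-high cells. RLE size factors and DESeq2 gave 659 and 677 calls for overexpression against WT. No filter on low counts gave 1187 (608 higher, 579 lower). Leaving out each library in turn gave 565 to 1584 calls (327 to 694 higher, 238 to 890 lower). For Ly6d-high against Ly6d-low, no filter on low TPM gave 531 calls (485 higher, 46 lower), a pseudocount of 0.1 gave 1278, and TMM factors gave 961 (712 higher, 249 lower), of which 828 were main calls in the same direction. Recovered reads gave 1815 calls with edgeR (591 lower, 1061 of the calls shared with the main test) and 1547 with DESeq2 (607 lower). Leaving out each library gave 931 to 6710 calls (833 to 5599 higher, 98 to 1111 lower). The cause of these moves was not tested. In no alternative of either comparison did a call of the main test change its direction.

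The replicate block gave 4179 calls (3581 higher, 598 lower) for Ly6d-high against Ly6d-low. The labels do not say that same-numbered libraries share an animal, and with 2 pairs their deviations, at a Pearson correlation of 0.0681 and a Spearman correlation of 0.186 across genes, do not decide it. No paired analysis was possible for overexpression against WT because the overexpression columns were matched to their group and not to single samples, so the numbers 1 and 2 in their names were not taken as the labels' replicate numbers. With an estimated correlation, 1 list was called for overexpression and 0 for Ly6d-high. Leaving out each library gave 12 to 22 lists, against 11, and 11 to 19 lists, against 16. The correlation of both effects was not stable: Pearson r was -0.00715 at a mean of at least 10 CPM and TPM and -0.192 without marker genes of other cell types, and leaving out each library gave -0.131 to 0.0816, with -0.0877 without Ly6d-high replicate 1. Spearman rho stayed between -0.0954 and -0.0245 over those. Among the named genes, 46 lost their call in Ly6d-high cells with no filter on low TPM, 31 with TMM factors, 8 with a pseudocount of 0.1, 13 with edgeR and 24 with DESeq2 on recovered reads, 34 without Ly6d-low replicate 1, 28 without Ly6d-low replicate 2 and 5 without Ly6d-high replicate 2. For overexpression, 17 lost it without WT replicate 1, 8 without WT replicate 2, 7 and 9 without overexpression replicates 1 and 2, and 1 (Mcm3) with DESeq2. Where a library is left out, the lone library of its group is assumed to vary like the other group. Depth limits genes near the floor: 3 counts correspond to 0.146 to 0.199 CPM in these libraries.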

Other observations

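Of the tests below, the opposite direction of acinar genes, and the pan-leukocyte genes in Ly6d-high cells without a level filter, were tested only after the results were seen. The others were set before their values were seen.

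Several genes outside the lists were lower with overexpression and higher in Ly6d-high cells, and are named here after their values were seen. The protease gene Prss8, which acts on epithelial sodium channels, had a log2 fold change of -2.10 with overexpression and a difference of 3.16 in Ly6d-high cells. The growth factor receptor genes Fgfr2 (-1.56 and 2.21) and Fgfr3 (-1.70 and 2.42), the serine protease gene Hpn (-1.84 and 4.26) and the antimicrobial lectin gene Reg3b (-2.17 and 2.29) did likewise. The acinar list moved in the same directions, and whether these transcripts came from tumour cells was not tested. In the opposite pairing, 4 genes rose with overexpression and were lower in Ly6d-high cells.

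Acinar transcripts fell with overexpression (median log2 fold change -3.79 over 29 genes) and were higher in Ly6d-high cells (median 1.05). A dependence on the Ly6d level would give both medians the same sign, since each comparison raised Ly6d. The medians had opposite signs, but this was the pattern already seen, so it is not independent evidence. It also bears on such a dependence only if the acinar reads came from the cells whose Ly6d differed. RNA of acinar cells in the sorted libraries is a candidate explanation. Across 28 acinar genes, the mean TPM in WT and in Ly6d-high libraries had a Spearman correlation of 0.906 (bootstrap interval 0.753 to 0.968), as a single profile would give, although acinar gene expression in tumour cells would give it too. The regulators Rbpjl and Bhlha15, named after their values were seen, fell with overexpression (-2.96 and -1.73). Rbpjl was higher in Ly6d-high cells (difference 1.01). A difference of the WT and overexpression tumours themselves stays open.

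Y-linked transcripts (Ddx3y, Eif2s3y, Uty and Kdm5d together) were at 33.9 and 32.5 CPM in the Ly6d-high libraries and at 2.06 and 1.71 in the Ly6d-low libraries, a median log2 ratio of 4.50. Reads shared with the X-linked copies would move these too, but their median log2 ratio was 0.00973 and the highest 0.32, which argues against that. Male plasma cells could carry such transcripts: the ratio between both Ly6d-high libraries was 1.16 (95% interval 1.04 to 1.299) for Y-linked reads, which cannot be told apart from the 1.29 (1.26 to 1.32) of immunoglobulin constant-region reads or from the 1.12 of all reads, and in overexpression libraries, as high in immunoglobulin reads (804 and 864 CPM) as Ly6d-high libraries (781 and 678 CPM), Y-linked reads were at 13.3 and 8.83 CPM against 18.1 and 16.0 CPM in WT. Male host duct cells were tested on 10 duct genes, whose median log2 ratio was 0.71 with quartiles of 0.42 and 2.79. Those named here were picked after their values were seen. They ran from Sctr (4.96), Onecut1 (4.70), Cys1 (3.36) and Bicc1 (1.08) to Scnn1a (-0.65), a spread that keeps this open. The Ly6d-low libraries, with few Y-linked reads, also held Kcne3 at 102 and 98.3 TPM and Onecut2 at 21.2 and 25.2 TPM. They held little Onecut1 (0.241 and 0.477 TPM). Some duct genes were thus expressed where Y-linked reads were few, so these genes could not tell host duct cells from tumour cells. With overexpression, where Y-linked reads were lower too, 8 of 10 tested duct genes were lower, with a median log2 fold change of -0.29. The sex of the animals is not in the labels, and loss of Y-linked expression in the Ly6d-low fraction, a difference between the sorted groups themselves, was not tested.

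Transcripts of the macrophage and plasma cell lists were higher with overexpression and in Ly6d-high cells, and those of the neutrophil list with overexpression. In Ly6d-high cells 4 of 7 tested neutrophil members were higher. Of these, epithelial cells also express Lcn2 and Ltf, Ly6g lost its call in several alternatives, and Lcn2 fell with overexpression (log2 fold change -0.72). None of these lists kept its camera call with an estimated correlation. Camera called neither the dendritic nor the cytotoxic and natural killer cell list in either comparison. It did not call the T cell list with overexpression, and that list had only 2 tested members in Ly6d-high cells. Leukocytes in the sorted cells would raise pan-leukocyte genes outside the marker lists as well. With overexpression, 24 of 24 such genes were higher, with a median log2 fold change of 2.20. In Ly6d-high cells 21 of 24 were higher by read sums, with sums under 3 reads set to 3 and a median log2 ratio of 1.58. Of the rest, named after their values were seen, Alox5ap was lower, and Was and Hcls1, at 3 reads or fewer per group, gave no direction. Some of the 21, also named after their values were seen, were weak or uneven. Coro1a and Cd52 were lower in Ly6d-high replicate 2 (1.35 and 0.887 TPM) than in Ly6d-low replicate 2 (1.74 and 1.21 TPM). Arhgap30 rested on 4 and 0 reads against 0 and 1, and Ncf4 on 37 and 3 against 4 and 2. The rise of the set in both comparisons would follow from leukocytes among the sorted cells, which a clean sort of tumour cells would remove. However, Ptprc, left out of this test, was at only 0.0817 and 0.172 TPM in the Ly6d-high libraries, while Igkc was at 1654 TPM in their mean. These Ptprc levels rest on 12 and 21 reads, against 7 and 6 reads (0.0633 and 0.0429 TPM) in the Ly6d-low libraries. Whether tumours of these groups held more leukocytes, or the sort let more through, was not tested. The overexpression columns were assigned to sorted cells from a library name that the labels use for overexpression tumours, which these values cannot check.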
